A study of Mus musculus with 14 samples.

How the data were processed

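RNA from sorted mouse regulatory T cells (Treg cells, the CD4 T cells that express the transcription factor Foxp3) was measured on 14 Affymetrix whole-genome mouse expression arrays, which are 1-colour arrays with 45101 probe sets. Per the labels, the cells came from knock-in mice of the 129/SvJ background (H-2b) whose Foxp3 locus also makes GFP, and were sorted for it. The 6 naive samples came from resting spleens. The 3 samples activated by graft-versus-host disease (GVHD) came from the spleens of BALB/c mice (H-2d) that had received 900 cGy, 2000000 donor T cells and 2000000 donor bone marrow cells, and were taken on day 4. The 5 allogeneic tumor-activated samples were taken from ascites in such knock-in mice 5 days after an intraperitoneal dose of 1000000 P815 cells, a mastocytoma line of DBA/2 origin (H-2d). The labels of naive replicates 4 to 6 and of both activated groups give a sort purity over 95%, and those of naive replicates 1 to 3 give none. The protocol attached to naive replicates 1 to 3 describes another tumor model beside the resting spleens.

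The authors extracted RNA with Trizol and labelled it with biotin, per the labels' protocols. Per the submitters' processing notes they computed the deposited intensity values with MAS5, the signal algorithm of the array's maker, whose version is not given in the sources used here. The deposited values are probe set intensities on a linear scale. Their mean without the lowest and highest 2% was 1500 in the 3 GVHD-activated arrays and 500 in the other 11, so the GVHD-activated arrays had been scaled 3 times higher. Naive replicates 1 to 3 were written with 7 significant digits and the other arrays with 1 decimal. The deposited values thus fall into 3 sets by scale and number format, and the GVHD-activated arrays and their own controls lie in different ones. Batch and group cannot be told apart for that comparison, because neither set holds arrays of both groups.

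Each array was rescaled to a 2% trimmed mean of 500, and log2 was taken after adding an offset of 32. A fold change is therefore on the log2(signal + 32) scale, which understates the change of dim genes. A probe set was kept where its scaled signal was at least 100 in at least 3 arrays. Gene names came from the platform annotation, in which 34958 of the 35890 listed probe sets had 1 gene symbol and 932 had several. Another 9160 probe sets, controls aside, had no entry and stayed unnamed. The Entrez number of 34754 of the 1-symbol probe sets matched the RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. Only probe sets with 1 symbol were used, and each gene was represented by its probe set of highest mean log2 signal. That left 22143 probe sets past the filter and 12212 genes. The genome build behind the array's design is not given in the sources used here, so no coordinates are printed.

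All tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, on a means model of 4 groups over all 14 arrays that share an estimate of the spread. The 3 activated-against-naive questions were GVHD-activated against naive replicates 1 to 3, tumor-activated against naive replicates 4 to 6, and the difference between these changes. The assignment of controls is the submitters' own. A further contrast set naive replicates 4 to 6 against 1 to 3. Benjamini-Hochberg adjusted p-values under 0.05 were called, and a gene is said to have risen or fallen only where it was. Every adjusted p printed for a gene is limma's. The titles call the samples biological replicates but do not say which came from separate animals, so the p-values measure the spread between these samples.

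Before the data were examined, 24 gene lists were fixed: cytotoxic effectors, Treg identity and suppression, cell cycle, naive and lymphoid homing, chemokine receptors and adhesion, inhibitory receptors and co-stimulation, T helper transcription factors, cytokines, interferon-stimulated genes, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, p53 targets and DNA damage, the unfolded protein response, immediate early and heat shock genes, markers of B cells, macrophages and monocytes, neutrophils and granules, mast cells and mastocytoma, erythroid cells and platelets, CD8 T and NK cells, dendritic cells, and stroma and mesothelium, and sex-linked transcripts. A further list of T cell receptor and lineage genes was added after the data were seen. Lists were tested with camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 24 lists of a contrast, and again with an estimated correlation. Fry, which tests a list's own shift rather than its shift against other genes, was run beside it. The added list was its own family of 1, so its adjusted p equals the raw p.

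Genes to be named were set by a rule fixed before the data were examined. In each of the 3 main contrasts these were the 8 largest rises and 8 largest falls among called genes whose 2 groups of arrays did not overlap and whose mean scaled signal was at least 200 in the highest group. For the contrast of the naive sets 3 of each were taken. From each list up to 3 called members per direction were taken, or up to 2 of the brightest where none was called. Foxp3, Il2ra, Ctla4, Gzma, Gzmb and Prf1 were always included. Of the 213 named genes, 18 had another probe set past the filter that moved the other way in a comparison that names them.

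The scripts were tested on simulated arrays with the real genes' means and spreads, 12212 genes and 100 genes changed by each size. In the GVHD comparison 76 of 100 genes changed by 2 on the log2 scale and 7 of 100 changed by 1 were recovered, with 2 calls among unchanged genes. In the tumor comparison it was 86 and 17, with 5 such calls, in the contrast of the naive sets 72 and 13, with 3, and in the difference 41 and 1, with 3. A shift of the cell cycle list was called in each simulated contrast, with 0 of the other lists called. The simulated genes were drawn independently of each other, with the same spread on every array. In the real data the estimated correlation reached 0.545 for Treg genes and 0.696 for the added T cell list. The simulation therefore cannot tell how often a correlated list is called without a shift. Precision is limited by the number of arrays. The alternatives set beforehand covered scaling, offset, filter, choice of probe set, variance model, array weights, the arrays in the fit, the choice of naive controls, the replicate number as a block, a 2-fold threshold and leaving out each array. Replicate numbers did not pair the arrays, so the main design has no block. Some of the listed genes were not analysed here.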

Results

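The series asked which transcripts change when Treg cells are activated in 2 allogeneic settings, GVHD and the ascites of an allogeneic tumor. Signals were obtained from 14 arrays: naive replicates 1 to 6, GVHD-activated replicates 1 to 3 and tumor-activated replicates 1 to 5. After scaling, 12212 genes were tested. Between 45.5% and 55.4% of probe sets reached a signal of 100 on 13 of the arrays, and 37.3% did on tumor-activated replicate 3. Correlations between arrays of a group ranged from 0.945 to 0.960 for naive replicates 1 to 3, 0.936 to 0.970 for naive replicates 4 to 6, 0.951 to 0.962 for GVHD and 0.835 to 0.983 for tumor. No array was a copy of another. The only probe set of Foxp3, the gene the cells were sorted on, read at most 108 on every array and did not pass the filter, so it does not check the sort.

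GVHD-activated Treg cells showed a rise of granzymes A and B and of cell cycle genes. Gzmb, the protease granzyme B of cytotoxic granules, went from a scaled signal of 612 ± 124 (SD, n = 3) in naive replicates 1 to 3 to 83732 ± 10003 (SD, n = 3), a 131-fold rise (log2 7.03, SE 0.47, adjusted p = 3.9e-08). Gzma, granzyme A, rose 76.5-fold, from 116 ± 114 to 8972 ± 1269 (SD, n = 3 each; adjusted p = 9.5e-07). Nkg7, a cytotoxic granule membrane protein, rose 37.7-fold. Prf1, the pore-forming protein perforin, rose 3.77-fold from 260 ± 40.7 to 1123 ± 424 (adjusted p = 0.0028). The exact permutation test of 3 arrays against 3 gave p = 0.1 for Gzma, Gzmb and Prf1 (two-sided), the smallest p this design allows, or 0.125 after adjustment over the 10 such tests run. With the mean over all probe sets of a gene, the change of Prf1 was 0.82 on the log2 scale and did not pass. Against naive replicates 4 to 6 Gzmb rose 41.6-fold and Gzma 41.8-fold, and Prf1 (log2 1.07) did not pass.

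In all, 1201 genes rose and 1526 fell in the GVHD comparison. The 8 largest rises were Gzmb, 1500009L16Rik, Bub1b, Gzma, Birc5, Aurkb, Rrm2 and Ccna2, of which Bub1b, Birc5 and Aurkb act in mitosis and Rrm2 is a subunit of the enzyme that makes deoxynucleotides. The 8 largest falls were Cd83, Aff3, Ntn4, Nsg2, Evl, Cyp4f18, Ramp1 and Ephx1, with Cd83 going from 4576 ± 556 to 34.0 ± 23.7 and Aff3 from 2157 ± 247 to 12.9 ± 5.71. In 2689 of the 2727 called genes the arrays of the 2 groups did not overlap. Over all genes tested, 5947 of 12212 were separated in this way, where chance gives 10%. Between the 2 naive sets, which by their labels hold the same kind of cell, 4889 of 12212 were separated by the same rule. The separation in GVHD therefore cannot be credited to activation alone.

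Of 29 measured cell cycle genes 28 rose and 0 fell in GVHD-activated cells (median log2 4.53, camera adjusted p = 1.24e-40; adjusted p = 4.32e-05 with an estimated correlation). Adjusted over the list alone, 29 rose. Birc5 rose 71.3-fold, Aurkb 63.5-fold and Rrm2 58.1-fold, or 30.0-fold, 5.93-fold and 6.15-fold against naive replicates 4 to 6, where the list median was 2.57. Of 13 cytotoxic effectors 6 rose and 1, Ctsw, fell (adjusted p = 0.00158; adjusted p = 0.113 with an estimated correlation), also 6 and 1 adjusted over the list alone, though Ctsw differed by 0.25 against naive replicates 4 to 6. Interferon-stimulated genes followed, with 15 of 30 rising and 1, Cxcl10 (at -1.14 against naive replicates 4 to 6, where it did not pass), falling (median 1.17, adjusted p = 1.55e-06; adjusted p = 0.111 with an estimated correlation), and 17 and 1 adjusted over the list alone. The 2',5'-oligoadenylate synthetases Oas1a, Oas3 and Oas2 rose 8.97-fold, 8.30-fold and 6.99-fold.

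Of 17 measured genes of naive cells and of homing to lymphoid organs, 8 fell and 1 rose (median log2 -1.40, adjusted p = 7.81e-06; adjusted p = 0.326 with an estimated correlation), with 12 and 1 adjusted over the list alone. Ccr7, the receptor that guides T cells into lymph nodes, fell from 7987 ± 1699 to 475 ± 84.8, and Evl and Foxp1 fell 27.5-fold and 14.9-fold. Rasgrp2 rose 3.93-fold. Inhibitory receptors and co-stimulation had 6 falls and 2 rises among 18 (adjusted p = 0.0424; adjusted p = 0.469 with an estimated correlation), also 6 and 2 adjusted over the list alone. Cd83, Tnfsf11 and Cd86 fell, while Havcr2, which encodes TIM-3, rose 11.8-fold from 77.4 ± 36.1 to 1219 ± 161. Against naive replicates 4 to 6 the inhibitory list had a median of -0.43 and did not pass, and Ccr7 fell 6.55-fold.

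Transcription factors moved both ways, with 7 of 25 rising and 7 falling (adjusted p = 0.99), or 8 and 7 adjusted over the list alone. Tbx21, the T-bet gene of T helper 1 cells, rose 7.59-fold, Prdm1, which encodes Blimp-1, 5.89-fold, and Runx3 4.88-fold. Id3 fell 13.8-fold, Egr2 7.14-fold and Nr4a2 6.15-fold. Of these, Prdm1 (log2 0.51), Runx3 (0.76) and Nr4a2 (-1.32) did not pass against naive replicates 4 to 6, and Tbx21 rose 3.63-fold. Among Treg genes 3 of 22 rose and 6 fell (adjusted p = 0.937), or 5 and 6 adjusted over the list alone. Entpd1, the ectonucleotidase CD39, rose 2.74-fold, while Nrp1, Gpr83 and Nt5e (the ectonucleotidase CD73) fell 11.4-fold, 11.2-fold and 10.1-fold. Il2ra read 3687 ± 811 in naive and 13941 ± 383 in GVHD-activated cells (adjusted p = 0.086), and Ctla4 24367 ± 2129 and 42620 ± 2952 (adjusted p = 0.2), so neither passed. For both genes the 2 groups of arrays did not overlap. The spread behind limma's p-values is shared by all 14 arrays, and tumor-activated replicate 3 widened it for both genes. That array read 460 for Il2ra and 3632 for Ctla4, against 4144 to 10913 and 8899 to 16594 in the other tumor-activated arrays. Not passing is therefore no sign that these genes stayed the same in GVHD. The exact permutation test gave p = 0.1 for each (two-sided), the smallest it can give, or 0.125 adjusted over the 10 such tests. Against naive replicates 4 to 6 Ctla4 passed (log2 1.37, adjusted p = 0.023) and Il2ra (1.78) did not. Chemokine receptors had 2 rises, Ccr2 (9.26-fold) and Ccr4 (2.49-fold), and 4 falls among 21 (adjusted p = 0.937), Ccr6 falling 17.4-fold, with 3 and 4 adjusted over the list alone. The rise of Ccr2 depended on the controls, since naive replicates 4 to 6 read 3017 and GVHD 2964 on average, a log2 change of 0.10 that did not pass. Cytokines had 2 rises, Ccl3 (5.31-fold) and Ifng (4.08-fold), and 2 falls, Ccl5 and Lta, among 15 (adjusted p = 0.937), the same counts as those adjusted over the list alone.

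The metabolic lists had more rises than falls in the GVHD comparison. Glycolysis and hypoxia genes had 10 rises and 2 falls among 22 (adjusted p = 0.000338; adjusted p = 0.111 with an estimated correlation), or 11 and 2 adjusted over the list alone, Tpi1 rising 5.19-fold and Bnip3 and Pdk1 falling. Oxidative phosphorylation had 7 rises among 27 (adjusted p = 1.96e-05; adjusted p = 0.524 with an estimated correlation), or 9 adjusted over the list alone, Cycs rising 2.75-fold. Cholesterol synthesis had 5 rises among 19 (adjusted p = 0.0163; adjusted p = 0.249 with an estimated correlation), or 6 adjusted over the list alone, with Cyp51 up 2.35-fold, but at a log2 change of 0.09 against naive replicates 4 to 6, which did not pass. In the unfolded protein response list 10 of 22 rose and 3 fell, as also adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.249 with an estimated correlation), Sdf2l1 rising 6.31-fold and Dnajb9 falling 4.42-fold. Among p53 targets 2 rose and 5 fell of 19, as also adjusted over the list alone (adjusted p = 0.821), and Cdkn1a, an inhibitor of the cell cycle, rose 9.75-fold. Immediate early and heat shock genes had 8 falls and 1 rise among 20 (adjusted p = 0.0876), or 13 and 3 adjusted over the list alone, Jun falling 12.8-fold. Against naive replicates 4 to 6 the list median was 0.44, and Jun (-0.56) and Dnajb9 (-1.19) did not pass, Jun reading 149, 291 and 5390 there and 381 to 529 in GVHD.

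Few markers of other cells changed in the GVHD arrays. Macrophage markers had 2 rises among 21, Fcgr3 and Lgmn, and mast cell markers 2 falls among 14, Gata1 and Mitf (adjusted p = 0.225 and 0.8). B cell markers had 0 calls among 11 by limma, Ighm reading 16154 ± 5520 and 19418 ± 3851 and 0 being called also adjusted over the list alone (1 at an unadjusted p under 0.05). Neutrophil, erythroid, CD8 T and NK, stromal and sex-linked lists had 1 fall each, in Il1r2, Car2, Crtam, Pecam1 and Kdm5d, and dendritic cell markers 2, Ccr7 and Zbtb46. The counts of these lists were the same adjusted over the list alone, and no list of other cells passed in the preset camera test. Against naive replicates 4 to 6 B cell markers did pass (median -1.54), and Fcgr3, Il1r2 and Pecam1 did not. Of the 18 added T cell receptor and lineage genes 0 were called by limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05, 1 up and 1 down (median -0.21, adjusted p = 0.908 in limma's camera, the list being its own family). The median and mean differed in sign for Treg genes (0.04 and -0.24), chemokine receptors (0.11 and -0.09), transcription factors (0.07 and -0.13) and CD8 T and NK markers (0.18 and -0.17). The cell cycle was the only list called in GVHD that kept its call with an estimated correlation. By fry every list called in GVHD passed, with adjusted p from 3.84e-11 (cell cycle) to 0.0446 (oxidative phosphorylation). Sex-linked transcripts passed by fry alone (0.0141).

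The GVHD-activated arrays and their controls had been scaled and written apart by the authors, so batch and group cannot be told apart here. Without rescaling 9072 genes rose and 235 fell, since the GVHD values had been deposited 3 times higher. With all arrays centred on the added T cell receptor and lineage genes, 303 genes rose and 264 fell, of which 291 and 255 were among those called above. The median of all genes was 0.10 there and -0.11 before, so the calls were not lost to a large shift of all genes. The mean of that list was 12.13 to 12.40 in GVHD and 12.43 to 12.50 in naive replicates 1 to 3, but 8.04 to 11.20 in the tumor-activated arrays. Centring therefore widened the spread of many genes between tumor-activated arrays, and all contrasts share that spread. The lower counts are thus no measure of the GVHD arrays alone. Centring and list were chosen after the data were seen. Fits to the 2 groups alone gave 2007 and 2593 and array weights 2026 and 2783, against naive replicates 4 to 6 1878 genes rose, a block on the replicate number gave 2407 falls, and without naive replicate 3 1015 fell.

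**Figure D1:**
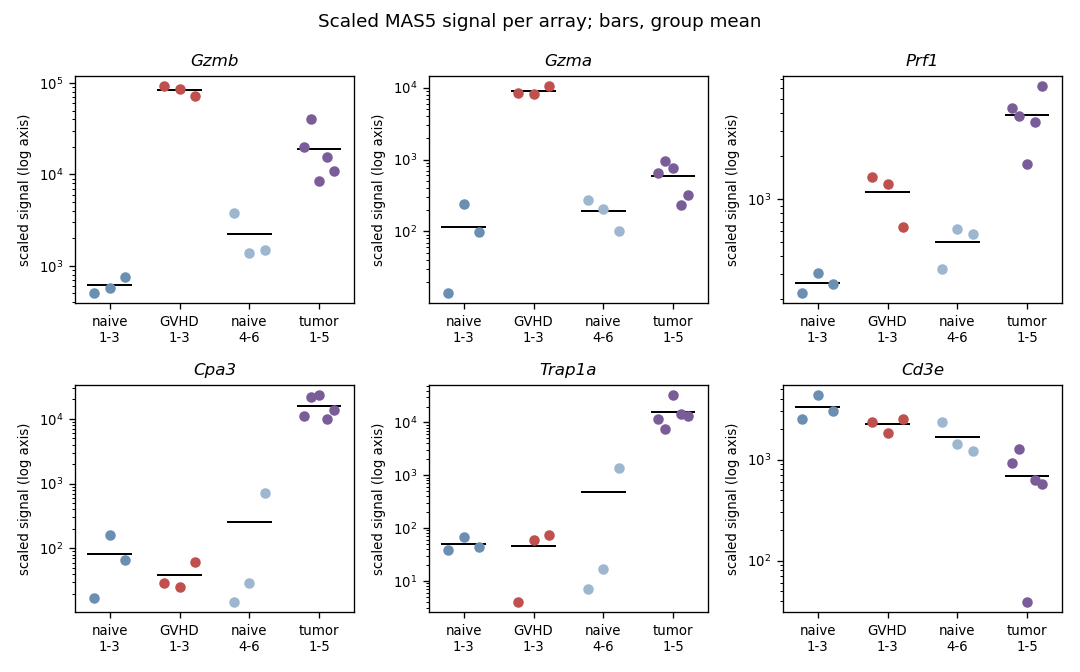
Scaled signal on each array (log axis) for 6 genes, with points for arrays and bars for group means. Gzmb and Gzma are highest in the 3 GVHD arrays, Cpa3 and Trap1a in the 5 tumor arrays, naive replicate 6 holds 1402 of Trap1a against at most 69 in the other naive arrays, and Cd3e is at 39 in tumor replicate 3.

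In tumor-activated samples the largest rises included genes of mast cells, of the P815 tumor and of macrophages. Cpa3, a mast cell protease, went from 252 ± 398 (SD, n = 3) in naive replicates 4 to 6 to 15899 ± 6129 (SD, n = 5), a 117-fold rise (log2 6.87, SE 0.69, adjusted p = 5.6e-06). Trap1a, the P1A tumor antigen of P815 cells, went from 475 ± 803 to 15974 ± 9723. Arg1, the arginase of alternatively activated macrophages, rose 144-fold to 29877 ± 5423. Among the controls, replicate 6 alone read 1402 for Trap1a and 4882 for Arg1, against at most 17 and 15 in replicates 4 and 5. The other leading rises were Mcpt8, Tph1, Rhox5, Rnase2a and Ctsg, from 84.9-fold to 106-fold. Without naive replicate 6 the rises were 281-fold for Cpa3, 325-fold for Trap1a, 706-fold for Arg1 and 172-fold to 332-fold for these 5.

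Of 14 mast cell and mastocytoma markers 10 rose and 0 fell in tumor-activated samples (median log2 3.74, adjusted p = 8.53e-09), and of 21 macrophage and monocyte markers 19 rose and 0 fell (median 3.65, adjusted p = 3.25e-12). With an estimated correlation the adjusted p was 0.0335 for mast cell and 0.0982 for macrophage markers. By fry it was 2.28e-06 and 6.85e-05. Both counts were the same adjusted over the list alone. Alox15, Marco and Adgre1 (the F4/80 antigen) rose 63.2-fold, 58.0-fold and 29.8-fold, or 184-fold, 140-fold and 51.6-fold without naive replicate 6. The added T cell receptor and lineage genes moved down, with 12 of 18 falling and 0 rising (median -1.90, adjusted p = 6.66e-06; adjusted p = 0.203 with an estimated correlation), and 16 falling adjusted over the list alone. That list was chosen after the data were seen. Cd5 fell from 15642 ± 5191 to 3926 ± 3177 and Cd6 from 10395 ± 4554 to 2467 ± 2485, and in tumor-activated replicate 3 Cd5 read 179, Cd3e 39 and Cd4 22. The 3' to 5' signal ratio of Gapdh, a sign of RNA quality, was 7.45 to 19.1 in naive replicates 4 to 6, 19.9 in tumor-activated replicate 2 and 2.19 to 2.64 in the other tumor-activated arrays.

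The tumor comparison called 1974 rising and 1895 falling genes. Without tumor-activated replicate 3 and naive replicate 6, an alternative chosen after the data were seen, it called 2022 and 1875. Without naive replicate 5 it called 1344 and 1018, in a fit to the 2 groups alone 1200 genes fell, and with array weights it called 3525 and 3592. The falls were 2942 against all 6 naive arrays and 3072 against naive replicates 1 to 3. The 2 groups of arrays did not overlap in 3344 of the 3869 called genes and in 4204 of all 12212, where chance gives 3.57%. With arrays centred on the added T cell list, 7823 genes rose and 55 fell, and 55 of the 1895 falling genes fell relative to T cell receptor and lineage genes. That centring moved the median of all genes from -0.06 to 1.65. Among the 8 largest falls, Dtx1, a regulator of Notch signalling, went from 12721 ± 966 to 640 ± 416, while Cd83 went from 3161 ± 550 to 111 ± 51.0. The others were Nsg2, St8sia1, Ntn4, Igha, Plagl1 and Lrig1, from 14.3-fold to 26.3-fold, Igha falling 10.1-fold without naive replicate 6.

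The signals of Gzmb and Prf1 rose here too, and which cells in the samples gave them was not tested. In tumor-activated replicate 3 Cd3e read 39 and Cd4 22, yet Gzmb read 8573 and Prf1 1770. No naive array read above 3778 for Gzmb or 618 for Prf1. Gzmb rose 8.22-fold, from 2208 ± 1361 to 19173 ± 12780 (adjusted p = 7.3e-05), and Prf1 7.05-fold, from 506 ± 159 to 3918 ± 1586 (adjusted p = 3.8e-05). A much dimmer probe set of Prf1 did not rise, reading 67, 94 and 68 in naive replicates 4 to 6 and 25 to 67 with the tumor. Gzma read 195 ± 86.8 and 588 ± 306 (adjusted p = 0.051) and did not pass. Against naive replicates 1 to 3 Gzma rose 4.72-fold (adjusted p = 0.0022), Gzmb 25.9-fold and Prf1 12.6-fold. Exact permutation tests of 5 arrays against 3 (two-sided) gave p = 0.0179 for Gzmb and Prf1, the smallest they can give, and 0.0536 for Gzma, or 0.0895, 0.0895 and 0.125 after adjustment over the 10 such tests run. Of 13 cytotoxic effectors 5 rose and 1, Fasl, fell (adjusted p = 0.0209; adjusted p = 0.221 with an estimated correlation), or 6 and 1 adjusted over the list alone. Nkg7 rose 4.20-fold.

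Cell cycle genes rose in 22 of 29 with 0 falls (median log2 1.28, adjusted p = 1.91e-10; adjusted p = 0.0082 with an estimated correlation), or 24 adjusted over the list alone. Tpx2 rose 5.90-fold, Cdk1 4.13-fold and Bub1 4.07-fold. Against naive replicates 1 to 3 they rose 16.3-fold, 18.5-fold and 27.8-fold, and the list median was 2.90. Glycolysis and hypoxia genes rose in 17 of 22 (median 1.55, adjusted p = 6.08e-12; adjusted p = 0.00641 with an estimated correlation), also 17 adjusted over the list alone. Bnip3, a hypoxia target, rose 16.7-fold, Tpi1 8.08-fold and Pgam1 6.46-fold. The unfolded protein response list had 14 rises and 0 falls among 22 (adjusted p = 2.55e-07; adjusted p = 0.0179 with an estimated correlation), or 16 adjusted over the list alone. Its leading genes Trib3 (9.40-fold), Asns (7.62-fold) and Chac1 (6.01-fold) are targets of ATF4 in the amino acid stress response. Oxidative phosphorylation genes rose in 7 of 27 (adjusted p = 0.000323; adjusted p = 0.556 with an estimated correlation), also 7 adjusted over the list alone, and did not pass without tumor-activated replicate 3 and naive replicate 6 (median 0.22). These lists rose in the same arrays as the mast cell and macrophage markers.

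Genes of naive cells and homing fell in 14 of 17, and 1, Igfbp4, rose (median log2 -2.25, adjusted p = 4.43e-07; adjusted p = 0.221 with an estimated correlation), the same counts as adjusted over the list alone. Evl, Bach2 and Dapl1 fell 12.6-fold, 10.9-fold and 7.91-fold. Transcription factors fell in 11 of 25 and rose in 2 (adjusted p = 0.00476; adjusted p = 0.556 with an estimated correlation), or 12 and 2 adjusted over the list alone. Id3 and Egr3 fell 11.5-fold and 8.87-fold, Egr2 fell by 3.17 on the log2 scale, and Nfil3 and Batf3 rose, Batf3 not passing without tumor-activated replicate 3 and naive replicate 6. Chemokine receptors and adhesion fell in 8 of 21 and rose in 1, Ccr1 (15.5-fold), for the list adjusted p = 0.0428 and adjusted p = 0.573 with an estimated correlation, as also adjusted over the list alone, with Ccr6 and Cxcr5 falling 5.72-fold and 5.30-fold. Ccr1 read 4082 in tumor-activated replicate 3 and at most 1446 in the other tumor-activated arrays, and which cells gave it was not tested. B cell markers fell in 7 of 11 (adjusted p = 0.00777; adjusted p = 0.406 with an estimated correlation), or 9 with 1 rise adjusted over the list alone, Ighm from 13246 ± 7049 to 2925 ± 2550. Sex-linked transcripts fell in 2 of 4, Kdm5d and Eif2s3y (adjusted p = 0.0292; adjusted p = 0.221 with an estimated correlation), or 3 adjusted over the list alone. These falls went with that of the T cell receptor and lineage genes. Relative to those genes, where the median of all genes was 1.65, the list medians were lower at 0.79 for transcription factors, 1.18 for chemokine receptors, 0.17 for B cell markers and 0.71 for sex-linked transcripts. Without tumor-activated replicate 3 and naive replicate 6 the medians of these 4 lists were -0.57, -0.39, -1.30 and -0.92 and none of the 4 passed, with 4 of the B cell markers falling. Against naive replicates 1 to 3 transcription factors, chemokine receptors and sex-linked transcripts did not pass, nor did cytotoxic effectors and oxidative phosphorylation, and the B cell median was 0.24. Of the genes named, Ccr6 (log2 -1.27), Nfil3 (0.64) and Eif2s3y (-0.26) did not pass there.

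Other lists did not pass as a whole in the tumor comparison. Treg genes had 3 rises and 7 falls among 22, as also adjusted over the list alone (adjusted p = 0.104; median -0.59, or 1.12 relative to the added T cell list, where all genes had 1.65), Tnfrsf9 rising 2.26-fold and Gpr83, Itgae and Nrp1 falling 9.18-fold, 5.23-fold and 5.20-fold, though Itgae (log2 -1.34) did not pass against naive replicates 1 to 3. Il2ra read 4071 ± 551 and 6181 ± 4270 (adjusted p = 0.98) and Ctla4 16875 ± 5007 and 11581 ± 5334 (adjusted p = 0.19). Against naive replicates 1 to 3 Ctla4 fell (log2 -1.25, adjusted p = 0.015). Its difference between the activations passed with the controls exchanged (-2.62, adjusted p = 0.0024). Inhibitory receptors had 4 rises and 6 falls among 18 (adjusted p = 0.235), as also adjusted over the list alone, Cd244a rising 15.7-fold and Pdcd1 (PD-1) 1.83-fold. Cytokines had 5 rises and 2 falls among 15 (adjusted p = 0.235), or 5 and 3 adjusted over the list alone. Il6, Il4 and Il13 rose 9.90-fold, 5.39-fold and 4.19-fold. They read 1643, 1361 and 403 in tumor-activated replicate 3, and at most 636, 494 and 229 in the other tumor-activated arrays. Cd244a read 10544 there and at most 5487 in the others. Replicate 3 read 39 for Cd3e and 22 for Cd4, and which cells gave these rises was not tested. Interferon-stimulated genes had 7 rises and 1 fall among 30 (adjusted p = 0.0716), or 5 and 1 adjusted over the list alone. In 19 p53 targets 4 rose, with Cdkn1a at 18.0-fold and Perp at 17.7-fold, and 7 fell. Cholesterol synthesis had 5 rises and 1 fall among 19, and immediate early genes 2 rises, with Ier3 at 27.0-fold, and 7 falls among 20, or 4 and 7 adjusted over the list alone. Tumor-activated replicate 3 and naive replicate 6 weighed on the immediate early list, whose median went from -0.88 to 0.20 without them, with 6 rises and 6 falls. Without naive replicate 6 alone the median was 0.04, so most of the move came with that array. Ctsg and Prtn3, Pf4, Fcer1g and Tyrobp, and Bst2 led 3 rises each in the neutrophil (10 measured), erythroid and platelet (9), CD8 T and NK (8) and dendritic (12) lists, whose adjusted p ranged from 0.404 to 0.457. Falling were Crtam and Cd8b1 (CD8 T and NK), Car2 (erythroid) and Ccr7 (dendritic), of which Cd8b1 and Car2 did not pass without tumor-activated replicate 3 and naive replicate 6. Pdcd1 (0.34) and Bst2 (0.71) did not pass against naive replicates 1 to 3. Without naive replicate 6 Cd244a rose 23.8-fold, Perp 27.5-fold and Ier3 43.1-fold. The neutrophil list had a median of -0.54 and a mean of 0.73. The stromal list had 0 calls among 8 by limma, also adjusted over the list alone (1 at an unadjusted p under 0.05), Acta2 differing by 0.31 on the log2 scale (adjusted p = 0.71).

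The changes in the 2 settings overlapped. In both, 582 genes rose and 749 fell, where independent lists of these sizes would share 194 and 237. In opposite directions, 9 genes rose in GVHD and fell with the tumor and 78 did the reverse, where independent lists would share 186 and 247. The comparisons have separate controls. In the tumor comparison the added T cell list fell too (median -1.90), and 55 of the 1895 falling genes fell relative to it. How far lower T cell RNA in the tumor-activated samples gave the shared falls was not tested. Across the 12212 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.451 and a Spearman rho of 0.485.

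Tested directly, 902 genes changed more upward with the tumor than in GVHD and 414 more downward, or 352 and 7881 without rescaling and 998 and 10 centred on the added T cell list. Gzmb (log2 difference -4.00, SE 0.63, adjusted p = 8e-04) and Gzma (-4.89, SE 0.76, adjusted p = 0.00075) were lower in the tumor change than in the GVHD change, while the difference for Prf1 was 0.90 (adjusted p = 0.35) and did not pass. With the controls exchanged the difference was -3.14 for Gzma, which passed, and -0.68 for Gzmb, which did not, while that for Prf1 was 2.59 and passed. Of 13 cytotoxic effectors 4 were lower and 1, Lamp1, higher (adjusted p = 0.125), as also adjusted over the list alone. The largest upward differences were in Cd5l, Cpa3, Mcpt8, Trap1a, Ctsg, Arg1, Klf4 and Rhox5, from 95.6-fold to 210-fold, or 225-fold to 851-fold without naive replicate 6. The largest downward ones were in 1500009L16Rik, Bub1b, Gzma, Mki67, Ccnf, Dtx1, Birc5 and Nusap1, of which Bub1b (-0.48) and Birc5 (-2.00) did not pass with the controls exchanged. Dtx1 read 12878 ± 780 and 12292 ± 1194 in naive and GVHD-activated cells. Without tumor-activated replicate 3 and naive replicate 6 the counts were 1327 and 750. They were 565 and 259 without naive replicate 5, 1396 and 775 without tumor-activated replicate 3, 2468 and 2276 with all 6 naive arrays, 2374 and 2401 with the controls exchanged and 2321 and 1564 with array weights. The falls were 275 without GVHD-activated replicate 2 and 890 with a block on the replicate number.

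Of 29 cell cycle genes 25 were lower in the tumor change than in the GVHD change (median log2 -2.62, adjusted p = 4.34e-31; adjusted p = 0.000148 with an estimated correlation), or 28 adjusted over the list alone. This depended on the controls. Naive replicates 4 to 6 read Mki67, a proliferation marker, at 6299 ± 2591 against 921 ± 107 in replicates 1 to 3, and the activated groups read 8395 ± 3553 with the tumor and 33574 ± 2406 in GVHD. With the controls exchanged the median became 0.13 and the list did not pass, and Mki67, Ccnf and Nusap1 stood at 0.52, 1.08 and 1.73. Mast cell markers were higher in 11 of 14 (median 4.09, adjusted p = 8.16e-11; adjusted p = 0.031 with an estimated correlation) and macrophage markers in 12 of 21 (median 3.00, adjusted p = 4.57e-09; adjusted p = 0.264 with an estimated correlation), or 11 and 16 with 1 macrophage marker lower adjusted over the list alone. T cell receptor and lineage genes were lower in 2 of 18, Cd3g and Lat (median -1.60, adjusted p = 2.03e-05; adjusted p = 0.227 with an estimated correlation), as also adjusted over the list alone. Without naive replicate 6 neither Cd3g nor Lat passed. Without that array and tumor-activated replicate 3, 7 of 18 were lower (median -1.11).

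Interferon-stimulated genes were lower in 6 of 30 (median -0.78, adjusted p = 0.00152; adjusted p = 0.335 with an estimated correlation), or 7 with 1 higher adjusted over the list alone, Oas1a by 6.40-fold. Transcription factors were lower in 5 of 25, with Tbx21 and Prdm1 8.89-fold and 9.04-fold lower, and higher in 2, Myc and Nfil3 (median -1.19, adjusted p = 0.0137; adjusted p = 0.524 with an estimated correlation), or 6 and 2 adjusted over the list alone. With the controls exchanged Prdm1 was at 0.92, Nfil3 at -1.41 and Cr2 at 0.83, while Tbx21 (-1.02), Myc (1.51) and Pdcd1 (0.89) did not pass. The transcription factor (median -0.73), glycolysis (0.75), unfolded protein (0.42) and B cell (1.60) lists did not pass there, and the interferon list did. Relative to the added T cell list the interferon, transcription factor and B cell medians were 0.72, 0.31 and 0.51, below the 1.51 of all genes. Glycolysis and hypoxia genes were higher in 6 of 22 (median 0.94, or -0.62 without rescaling; adjusted p = 0.000516; adjusted p = 0.11 with an estimated correlation), or 10 adjusted over the list alone, with Bnip3 58.3-fold higher. The unfolded protein response list was higher in 7 of 22 (median 0.27, or -1.32 without rescaling; adjusted p = 0.0472; adjusted p = 0.403 with an estimated correlation), also 7 with 1 lower adjusted over the list alone, and B cell markers were lower in 1 of 11, Cr2 (adjusted p = 0.0192; adjusted p = 0.462 with an estimated correlation), or 2 adjusted over the list alone. Without tumor-activated replicate 3 and naive replicate 6 the unfolded protein (0.40) and B cell (-0.82) lists did not pass, while the immediate early list did, with 8 of 20 higher and a median of 1.29, and so did oxidative phosphorylation (-0.39). The immediate early list also passed without naive replicate 6 alone (median 0.99). Among single genes of lists that did not pass, Havcr2 was 6.25-fold lower, Igfbp4 59.1-fold and Pdcd1 3.89-fold higher. The median and mean differed in sign for cytotoxic effectors (0.01 and -0.91), naive and homing genes (-0.74 and 0.08) and neutrophil markers (-0.14 and 0.61).

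The naive sets, which by their labels hold the same kind of cell, differed in 960 genes, 541 higher and 419 lower in replicates 4 to 6, or 151 and 2 centred on the added T cell list. Cell cycle genes were higher in 18 of 29 and lower in 0 (median log2 1.52, adjusted p = 4.2e-18; adjusted p = 0.00157 with an estimated correlation), or 20 and 1 adjusted over the list alone, Aurkb by 10.7-fold and Rrm2 by 9.45-fold. The Gapdh 3' to 5' ratio was also higher in these arrays, at 19.1, 9 and 7.45 in replicates 4, 5 and 6 against 4.27 to 5.11 in replicates 1 to 3. Immediate early and heat shock genes were lower in 8 of 20 (adjusted p = 0.00247; adjusted p = 0.655 with an estimated correlation), or 11 adjusted over the list alone. Replicate 6 stood apart, with a mean log2 signal of the list of 12.57 against 11.14 and 11.08 in replicates 4 and 5 and 12.53 to 12.65 in replicates 1 to 3, and Jun read 5390 there against 149 and 291. Junb, an early response transcription factor, read 1311 ± 598 against 17308 ± 4436, and Ppp1r15a and Rps15 were 10.9-fold and 9.27-fold lower. B cell markers were higher in 3 of 11 (adjusted p = 0.000615; adjusted p = 0.655 with an estimated correlation), or 6 adjusted over the list alone, Ms4a1, the CD20 gene, at 1303 ± 764 against 116 ± 56.0. Without naive replicate 6 no B cell marker was called, though the list passed (median 1.04). Of 12 dendritic cell markers, 3 class II genes were higher, H2-Aa by 10.9-fold, and Ccr7 lower, and H2-Aa alone of these passed without naive replicate 6. Interferon-stimulated genes were lower in 3 of 30 (median -0.56, or 0.12 relative to the added T cell list, where all genes had 0.61; adjusted p = 0.0243; adjusted p = 0.655 with an estimated correlation), or 6 with 1 higher adjusted over the list alone. Rad51ap1, Shcbp1 and Serpinb1a were 11.6-fold, 11.4-fold and 11.3-fold higher. Serpinb1a read 341, 125 and 3520 in naive replicates 4, 5 and 6, 13 to 34 in replicates 1 to 3 and 19147 to 35944 with the tumor, and was 4.60-fold higher, which passed, without naive replicate 6. Gzmb was 3.15-fold higher (adjusted p = 0.043), but did not pass without that array. The added T cell list had 2 falls, Lcp2 and Lat (median -0.76, adjusted p = 0.00521; adjusted p = 0.418 with an estimated correlation). Without naive replicate 6 the counts were 236 and 118, and without replicates 1, 2, 3 and 5 264 and 163, 264 and 153, 268 and 161 and 211 and 84. Fits to the 2 sets alone gave 1248 and 1111 and array weights 2414 and 2834, quantile normalization gave 826 rises, and the mean over probe sets 348.

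**Figure D2:**
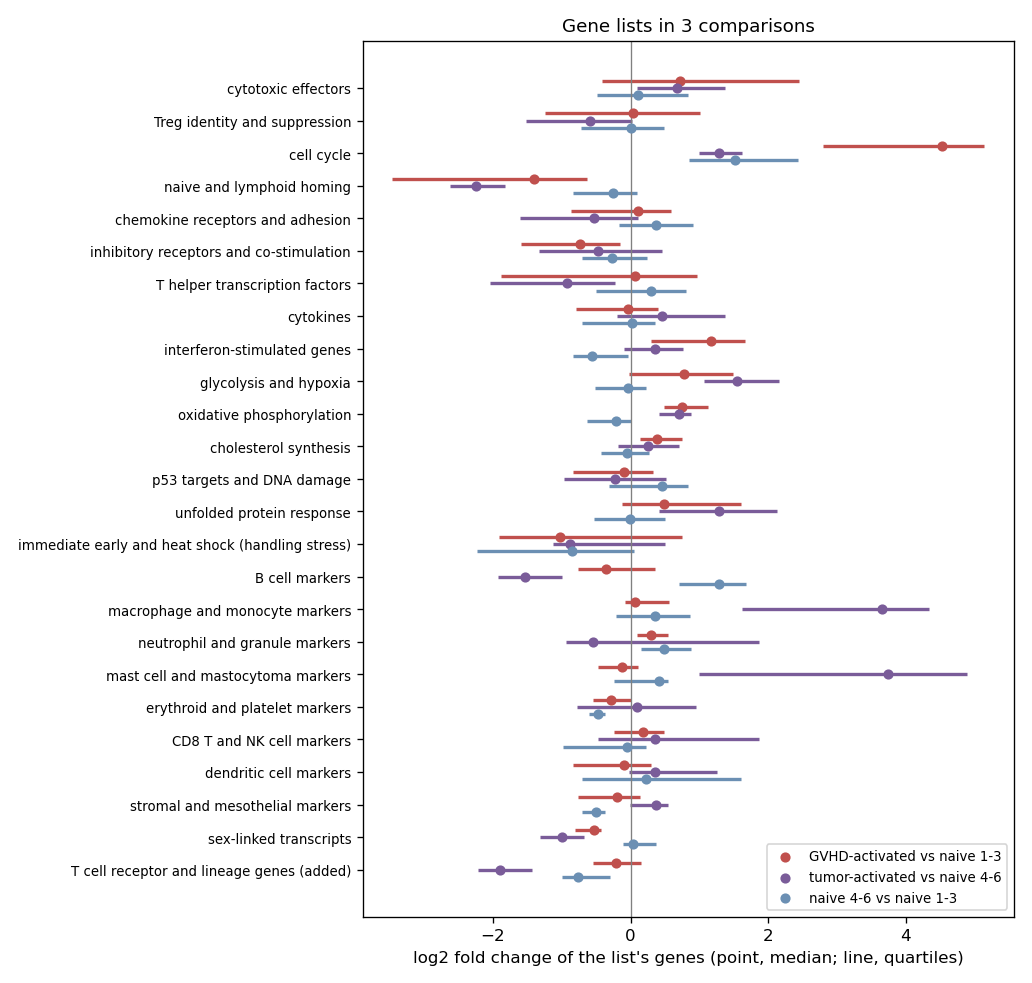
Log2 fold changes of the genes of each list (x axis; y axis, lists) in the GVHD, tumor and naive-set comparisons, with points for medians and lines for quartiles. The cell cycle list has its highest median in GVHD (4.53), the mast cell and macrophage lists stand at 3.74 and 3.65 with the tumor, and the added T cell list is at -1.90 there and -0.21 in GVHD.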

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

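Of the tests below, that of the cell cycle genes without naive replicate 6 and the counts over other splits of the arrays were set out before their results were seen, and the others, with the added T cell list, were chosen after.

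Transcripts of mast cells and macrophages stood beside lower T cell transcripts in the tumor-activated arrays. The added T cell receptor and lineage genes had a median log2 change of -1.90 against naive replicates 4 to 6, which is consistent with RNA from tumor cells and macrophages in samples sorted for GFP at a stated purity over 95%. Of the H2-D1 probe sets, 3 read at least 4698 on every tumor-activated array and at most 345 in naive replicates 1 to 5 and GVHD, which goes with P815 RNA if they detect the H-2d allele, but the annotation used here names no allele. Tumor-activated replicate 3 had the lowest mean of the T cell list (log2 8.04, against 10.07 to 11.20 in the others). Its mast cell and macrophage means were the highest (10.64 and 11.18, against 9.98 to 10.36 and 9.75 to 10.67). Less Treg RNA in that sample would give this. The other arrays differed the same way in smaller steps. Replicates 1 and 2 had T cell means of 10.93 and 11.20, against 10.07 and 10.12 in replicates 4 and 5. Mast cell means were 9.98 and 10.13 in replicates 1 and 2, against 10.28 and 10.36 in replicates 4 and 5. Macrophage means were 10.09 and 9.75 against 10.55 and 10.67. Within each of these pairs the order did not hold throughout. For the other transcripts, those of macrophages among them, transcription by the Treg cells stays open, since the median of -1.60 in the difference from GVHD would also be met if Treg cells in ascites lowered T cell genes. The mast cell list was fixed in advance, and its 3 leading genes, Cpa3, Mcpt8 and Tph1, rose 117-fold, 106-fold and 100-fold, or 281-fold, 232-fold and 296-fold without naive replicate 6.

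Naive replicate 6 held transcripts of the ascites samples that read low in naive replicates 4 and 5. Of 36 genes at 2000 or more in the tumor-activated arrays and under 100 in naive replicates 1 to 5, 33 were above 100 in naive replicate 6, at a median of 7.89% of their tumor mean. The interquartile range of the log2 ratio was 1.11, which is consistent with carry-over of ascites RNA or cells at 1 share for most of these genes. Spleen macrophages alone are argued against, because the mast cell markers that rose with the tumor lay 2.23 (log2) above naive replicates 4 and 5. A label swapped with a tumor-activated array is argued against too, since the T cell receptor and lineage genes lay within 1 (log2) of naive replicates 4 and 5 (median difference -0.38).

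Cell cycle genes were higher in naive replicates 4 to 6 than in 1 to 3 by a median of 1.52 (log2). Ascites material in naive replicate 6 is argued against, since the median was 1.71 without that array. A difference between batches and one between the cells cannot be told apart, because the sets differ in their deposited format, and 7.86% of the genes tested differed. The Gapdh 3' to 5' ratio, a sign of RNA quality, differed too (7.45 to 19.1 against 4.27 to 5.11), and its part was not tested. No biological explanation was tested.

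In the tumor comparison 1 of 56 splits of the 8 arrays, the real one, called as many genes (3869, highest other 2766). That share is under 0.05 and the smallest these splits allow, which argues against chance without excluding it. The highest other split set tumor replicates 3, 4 and 5 against the rest, so it holds part of the tumor change too. In the difference between the activations 3 of 56 splits called as many genes (1316, highest other 2180), so chance cannot be excluded by this count. The larger ones set tumor replicates 1, 4 and 5 (2180) or 3, 4 and 5 (2087) against the other 2 and all 3 GVHD-activated arrays. Their counts thus hold the difference itself and are not values without a change, so the count of splits does not settle it either way. The 10 splits of the GVHD comparison (1 as large; 2727, highest other 8) and of the naive sets (1 as large; 960, highest other 0) are too few for a share under 0.05.

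In the tumor-activated group the array farthest from the others stood apart by more than Dixon's 95% critical value in 4 of 25 lists, 8 of 37 genes and 3 of 5 quality measures, where chance alone does so in about 1 in 20 groups. Replicate 3 was the array apart for transcription factors (gap over range 0.751), p53 targets (0.76), immediate early genes (0.738) and CD8 T and NK markers (0.757). It was also apart for Birc5 (0.891), Arg1 (0.733), Mcpt8 (0.713), Tph1 (0.779), Dtx1 (0.713), Lrig1 (0.729) and the percent of probe sets at 100 or more (0.788). Replicate 2 was apart for Rrm2 (0.772), Cd83 (0.732) and the 3' to 5' ratios of Gapdh (0.975) and Actb (0.856).

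The test of the difference between the activations singled out 902 genes higher and 414 lower in the tumor change. Among the lists it singled out the cell cycle (median -2.62), transcription factors (-1.19), interferon-stimulated genes (-0.78), glycolysis (0.94), the unfolded protein response (0.27) and markers of B cells (-0.99), macrophages (3.00) and mast cells (4.09). Of these, only the cell cycle and mast cell lists kept their calls with an estimated correlation (camera adjusted p = 0.000148 and 0.031). By fry, transcription factors (adjusted p = 0.259) and B cell markers (0.0931) did not pass and the others did. The named genes higher were Cd5l (7.71), Cpa3 (7.37), Mcpt8 (7.09), Trap1a (6.86), Ctsg (6.84), Arg1 (6.67), Klf4 (6.64) and Rhox5 (6.58). Those lower were 1500009L16Rik (-7.12), Bub1b (-4.99), Gzma (-4.89), Mki67 (-4.76), Ccnf (-4.74), Dtx1 (-4.59), Birc5 (-4.50), Nusap1 (-4.40) and Gzmb (-4.00).

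Some signals lay outside the genes tested. Of 4778 probe sets that name no gene or several, 164 rose and 762 fell in GVHD, and 293 rose and 1577 fell with the tumor. For H2-D1, 3 probe sets of this class I gene, which differs between H-2b and H-2d mice, read 5769 ± 1535, 7556 ± 1581 and 8567 ± 1839 (SD, n = 5) with the tumor, against at most 228, 190 and 345 in the naive replicates 1 to 5 and GVHD arrays. In naive replicate 6 they read 332, 291 and 344.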

How the results depend on the processing

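Centring on the T cell list and leaving out both tumor replicate 3 and naive replicate 6 were chosen after the data were seen, and the other alternatives before. Counts are rising and falling genes, and unless a reason is given the cause was not tested.

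Without rescaling, GVHD gave 9072 and 235 and the difference 352 and 7881, because the GVHD values were deposited 3 times higher (median of all genes 1.32 and -1.43). There the GVHD values of Cd44, Atf4 and the naive, inhibitory, immediate early and mast cell lists became 0.16, 0.79, 0.16, 0.77, 0.55 and 0.80. In the difference Lamp1, Cd44, Itga2b and the cytokine, glycolysis, unfolded protein and CD8 T and NK lists became -0.48, -0.04, -0.14, -0.93, -0.62, -1.32 and -0.64. Quantile normalization moved the GVHD and tumor medians of all genes to 0.06 and 0.08 and gave 826 rising genes in the naive sets. The mean over probe sets gave 348 there. Without _x_at and _s_at probe sets Lss with the tumor was -0.45.

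Array weights, whose estimate stopped before full convergence, gave 2026 and 2783 (GVHD), 3525 and 3592 (tumor), 2321 and 1564 (difference) and 2414 and 2834 (naive sets). Fits to the groups compared alone gave 2007 and 2593, 1200 falling with the tumor, and 1248 and 1111 for the naive sets. They equal the main model for the difference. A replicate block gave 2407 falling in GVHD and 890 in the difference, could not be fitted for the naive sets, and used numbers that do not pair the arrays (correlations 0.059, 0.103 and -0.058 in GVHD, -0.504 and 0.062 with the tumor).

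With all 6 naive arrays the tumor falls were 2942 and the difference 2468 and 2276, with Atf4 at 0.07 in GVHD and Ccr2 and B cell markers at 0.34 and 0.31 in the difference. With the naive sets exchanged GVHD rises were 1878, tumor falls 3072 and the difference 2374 and 2401. There Ctsw, Ddit3, Atf4 and Dusp1 in GVHD were 0.25, 0.11, 0.92 and 0.33, and Atp5o, Ms4a1 and B cell markers with the tumor -0.14, 1.06 and 0.24. In the difference Mki67, Ccnf, Nusap1, Btla, Ccr2, Nfil3, Prdm1, Cr2 and Eif2s3y were 0.52, 1.08, 1.73, 0.59, 3.45, -1.41, 0.92, 0.83 and 1.33, and cell cycle genes and B cell markers 0.13 and 1.60.

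Centring on the T cell list gave medians of all genes of 0.10 in GVHD, 1.65 with the tumor, 1.51 in the difference and 0.61 in the naive sets. It gave 303 and 264 in GVHD, 7823 and 55 with the tumor, 10 falling in the difference and 151 and 2 in the naive sets. By its construction it raises every gene against lower T cell genes. With the tumor Fasl, Ccl5, Ifit2, Dhcr7, Btg1, Car2, Cd8b1, Kdm5d, Eif2s3y and Ctla4 became 0.44, 0.34, 0.65, 0.47, 0.16, 0.58, 0.54, 0.21, 0.44 and 1.02. The Treg, chemokine, inhibitory, transcription factor, B cell and sex-linked lists became 1.12, 1.18, 1.23, 0.79, 0.17 and 0.71. In the difference Ccr8, Lat and the chemokine, transcription factor, interferon and B cell lists became 0.01, 0.48, 0.51, 0.31, 0.72 and 0.51, and interferon genes in the naive sets 0.12. Without both doubted arrays 750 genes fell in the difference.

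Leaving out each array gave 870 to 1052 rising and 1015 to 1263 falling genes in GVHD, 1344 to 2289 and 1018 to 2209 with the tumor, 565 to 1396 and 259 to 775 in the difference and 211 to 467 and 84 to 406 in the naive sets. Naive replicate 5 was behind 1018, 565, 259, 211 and 84, tumor replicate 3 behind 1396 and 775, naive replicate 3 behind 1015, and without GVHD replicate 2 the difference had 275 falls. The naive sets gave 264 and 163, 264 and 153, 268 and 161 and 236 and 118 without naive replicates 1, 2, 3 and 6.

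Over all named genes and alternatives, the call was lost with the direction kept 152 times in GVHD, 157 with the tumor, 184 in the difference and 229 in the naive sets. Another 7 values in GVHD, 13 with the tumor and 15 in the difference changed sign where the main value or the alternative passed. In the same order, 1767, 2464, 2043 and 927 values of GVHD, tumor, difference and naive sets kept their direction and side of the threshold. Signals near the offset of 32 limit what can be read from dim genes.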

Other observations

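The tests of lists below were fixed before the data were examined, and none was added for them.

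Several gene groups differed between the activations in single members. Higher and lower here mean the tumor change against the GVHD change, each from its own controls. Cytokines were higher in 3 of 15, Il6, Lta and Il4 by 10.1-fold, 7.28-fold and 5.06-fold, and lower in 0 (adjusted p = 0.148). For Lta this came with its fall in GVHD, from 1075 to 1313 in naive replicates 1 to 3 to 78 to 280. With the tumor Lta read 564 to 979, against 653 to 813 in naive replicates 4 to 6. Which cells gave the tumor signals of Il6 and Il4 was not tested. Inhibitory receptors were higher in 4 of 18 and lower in 2 (adjusted p = 0.242), Cd244a being 9.20-fold higher and Tnfrsf1b 4.88-fold lower. Among Treg genes Nt5e and Fgl2 were 7.59-fold and 3.68-fold higher and Icos 6.25-fold lower (adjusted p = 0.125 for the list). Nt5e fell in GVHD, from 1481 to 1993 in naive replicates 1 to 3 to 70 to 202. It read 1064 to 1653 in naive replicates 4 to 6 and 333 to 2021 with the tumor. With the controls exchanged Icos (-1.19) and Tnfrsf1b (-1.64) did not pass. In the p53 list Perp, a p53 target in cell death, was 17.9-fold higher, and Ier3 was 16.6-fold higher in the immediate early list. Without naive replicate 6 Perp and Ier3 were 27.8-fold and 26.5-fold higher and Cd244a was at 3.80 on the log2 scale. There Il4 (log2 2.33), Fgl2 (1.84), Icos (-2.79) and Tnfrsf1b (-2.25) did not pass. Oxidative phosphorylation and cholesterol synthesis had 0 calls in limma among 27 and 19, and 0 and 1 at an unadjusted p under 0.05 (adjusted p = 0.472 and 0.242).

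Between the naive sets, Ccr2, a chemokine receptor of activated and effector cells, was 8.65-fold higher in replicates 4 to 6, and Swap70, which did not pass without naive replicate 6, 4.52-fold higher. Il10 was 5.05-fold (7.97-fold without naive replicate 6), Ctsw 4.40-fold and Mx2 4.90-fold lower. The lists of Treg genes (adjusted p = 0.859), cytotoxic effectors (0.821) and chemokine receptors (0.408) did not pass there.

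The 3' to 5' signal ratio of Gapdh was 19.1 in naive replicate 4, 9 in replicate 5, 7.45 in replicate 6 and 19.9 in tumor-activated replicate 2, and 2.19 to 5.11 in the other arrays. The median scaled signal was 52.0 in tumor-activated replicate 3 and 73.4 to 123 in the others.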
